A study of Rattus norvegicus with 9 samples.

How the data were processed

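RNA sequencing measured gene expression in 9 rat brain libraries, 3 in each of 3 groups. Per the labels, rats were divided at random. IR libraries came from rats with middle cerebral artery occlusion, a model of ischemic stroke, and the series' title speaks of ischemia and reperfusion. Sham libraries came from rats that had the surgery without the occlusion, with phosphate-buffered saline as their treatment label. IR+NMN libraries came from rats with the occlusion that were injected with nicotinamide mononucleotide (NMN), a precursor of the coenzyme NAD, at 100 mg/kg. The brain region, the time after surgery and the timing of the injection are not given in the sources used here. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these libraries, which may be technical. Total RNA was amplified by the Smart-Seq2 method, per the labels' protocols, which accepted an RNA integrity number down to 5.8.

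The deposited table held TPM, a length-scaled share of the transcripts, the authors' own normalized values, with each library summing to 1000000. The submitters' processing notes name STAR, Cufflinks and the human build hg38, although the samples are from rat. Tool versions and the annotation are not given in the sources used here, and no coordinates were used. The table had 131003 rows. A gene symbol stood in 27683 of them, a dash in 40459 and a blank in 62861, of which 8235 were above 0 in at least 1 library. Rows with a symbol held 72.7% to 78.7% of the TPM of a library, and the others stayed out of the tests. The rows carried 12609 symbols, of which 6395 had a single row, and rows of the same symbol were summed. Values of 612 rows repeated those of another row. Symbols were looked up in a gene table of the rat assembly GRCr8, which held 12314 of them. TPM keeps no sequencing depth, so the depth behind each value is unknown, and neither counting intervals nor detection floors could be given. A count test had been planned in case the table held counts, and the test planned for normalized values was used because it held TPM.

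Genes with at least 1 TPM in at least 3 of the 9 libraries were tested, which left 10180. Values were transformed as log2(TPM + 1), so a fold change on this scale understates the change of weakly expressed genes. A linear model with 1 mean per group was fitted to all 9 libraries with limma 3.58.1 (R 4.3.3, data.table version 1.17.8), with an intensity trend and robust moderation of the variances. The fit had 6 residual degrees of freedom, and a contrast of 2 groups therefore also depended on the spread within the other group. The 3 contrasts were IR against Sham, IR+NMN against IR, and IR+NMN against Sham. P-values were two-sided and adjusted within each contrast by the Benjamini-Hochberg method, with a threshold of 0.05. All adjusted p-values of genes and lists came from limma.

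Of 37 gene lists, covering processes, brain cell types and signs of dissection or blood, 34 had at least 5 tested genes. These were tested with the competitive camera test of limma at a preset correlation between genes of 0.01, adjusted over the 34 lists within each contrast. Because the test is relative to all other genes, a list can be called higher while its own median is near 0. Each test was repeated with the correlation estimated from the data, and with the fry test, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. With an estimated correlation 0 lists were called in any contrast, and the smallest adjusted p-values were 0.236 for IR against Sham, 0.0812 for IR+NMN against IR and 0.128 for IR+NMN against Sham. The fry test called 8, 14 and 19 lists in these contrasts. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Neutrophil markers (3 tested genes), lymphocyte markers (4) and mitochondrially encoded genes (0) were too few to test as lists.

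Genes named in the text followed a rule. It took, per contrast, up to 10 rising and 10 falling genes with the largest fitted change among those past the threshold. Their 3 libraries in 1 group all lay beyond the 3 of the other, the higher group averaged at least 5 TPM, and clone or number names were left out. Where fewer than 5 passed in a direction, the 5 with the smallest p were taken. It also took 25 genes chosen for the title's question, of which 21 were in the table, and up to 4 members with the smallest p in each list described. Single results of 2 genes taken by this rule are not reported here. The symbols Mpo, Elane, S100a8 and Sirt1 were not analysed here. The lists, the naming rule, the tests and most alternatives were fixed before the data were examined.

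To compare the response to ischemia, a score was computed from the 200 genes with the smallest p between Sham and 2 of the 3 IR libraries. It was the mean over genes higher in IR less the mean over genes lower in IR, centred on Sham. It was read in the IR library left out and in the IR+NMN libraries, and averaged over the 3 choices. Correlations between contrasts that share libraries were set beside 100 simulated draws with no group effect. Single values were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 libraries against 3.

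The gene test was run on simulated data made from the real means and spreads of the 10180 genes, with 200 genes changed and a further list of genes shifted. For IR against Sham it recovered 70.1% of genes changed 2-fold, 97.0% of those changed 4-fold and 100% of those changed 8-fold, with 12 false calls among 205. For IR+NMN against IR the shares were 83.6%, 97.0% and 100%, with 4 false calls among 207. For IR+NMN against Sham they were 73.1%, 100% and 97.0%, with 9 false calls among 207. Means and spreads of single genes carry neither correlation between genes nor shifts of a whole library. These shares and false calls therefore show how the test behaves on such simulated data, and give no error rates for the real libraries. Why they differed between the contrasts was not tested.

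Alternatives fixed beforehand were the replicate number as a block, leaving out each library in turn, quantile normalization, median-of-ratios scaling of the gene tests, other filters and pseudocounts, no intensity trend, library weights, a fit to only the groups compared, and a minimum change of 2-fold. Chosen after seeing the data were the highest row per gene, rescaling over rows with a symbol, the share of TPM in ribosomal protein genes as a covariate, leaving out genes with a row present in every library of Sham and near 0 in all others or the reverse, and median-of-ratios scaling of the list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.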

Results

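Gene expression was profiled by RNA sequencing in 9 rat brain libraries, 3 each from sham-operated rats (Sham), rats with middle cerebral artery occlusion (IR), and such rats given NMN (IR+NMN). Between 9741 and 10120 genes reached 1 TPM per library, and the sequencing depth behind the TPM values is unknown. The groups did not overlap in this number, with 10045 to 10120 in Sham, 9741 to 9877 in IR and 9918 to 9998 in IR+NMN. The two-sided exact permutation p was 0.1 in each contrast, the smallest possible. Spearman correlations across genes ranged from 0.973 to 0.985 among Sham, from 0.975 to 0.991 among IR and from 0.954 to 0.981 among IR+NMN libraries. Between groups they ranged from 0.958 to 0.979 for Sham with IR, from 0.945 to 0.986 for IR with IR+NMN and from 0.927 to 0.978 for Sham with IR+NMN. The first principal component held 42.7% of the variance and the second 21.7%. The groups were not cleanly separated. IR+NMN 2 correlated more closely with IR 1 (0.986) than with IR+NMN 1 (0.954) or IR+NMN 3 (0.977). IR 1 correlated about as closely with Sham 1 (0.979) as with IR 2 (0.979) and IR 3 (0.975). On the first component IR 1 (0.117) and IR+NMN 2 (0.0694) lay on the side of the Sham libraries, opposite the other IR and IR+NMN libraries. Ribosomal protein genes took 6.45% ± 0.761 of the TPM in Sham, 8.16% ± 1.62 in IR and 9.30% ± 2.56 in IR+NMN (SD, n = 3), with two-sided exact permutation p = 0.2 for IR against Sham, 0.6 for IR+NMN against IR and 0.1 for IR+NMN against Sham. Group values below are mean TPM ± SD with n = 3, changes are log2 differences of TPM + 1 with their standard error (SE), adjusted p-values are from limma, and libraries are named by group and replicate number.

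The comparison of IR with Sham addressed the effect of the occlusion. Hsp90aa1, a cytosolic chaperone, was higher in IR, at 2151 ± 165 TPM against 1066 ± 86.4 in Sham (log2 change 1.01, SE 0.12, adjusted p = 0.00460). The metal-binding protein Mt2A rose from 129 ± 26.3 to 707 ± 100.1 TPM (2.46, SE 0.18, adjusted p = 3.02e-04) and the interferon-induced gene Ifi27 from 71.0 ± 7.13 to 366 ± 32.4 TPM (2.35, SE 0.16, adjusted p = 1.42e-04). Ttr, the transthyretin gene of the choroid plexus, fell from 31.3 ± 7.38 to 0.708 ± 0.0155 TPM, and Rbm3, a cold-induced RNA-binding protein, from 104 ± 11.6 to 16.2 ± 2.28 TPM. The ribonuclease gene Rnase4 fell from 46.1 ± 2.04 to 7.08 ± 1.48 TPM and Zdhhc22 from 15.6 ± 5.41 to 1.87 ± 0.444 TPM. These 7 genes stayed past the threshold without any single library.

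In the list of heat shock genes, 7 of 19 rose over all genes and 10 adjusted over the list alone (adjusted p of the list = 9.49e-13, and adjusted p = 0.236 with an estimated correlation). Beside Hsp90aa1 these included its co-chaperones Dnaja1 (0.79, SE 0.11) and Ahsa1 (0.57, SE 0.11), and the small heat shock protein Hspb8 (0.95, SE 0.17). Dnaja1 missed the threshold without Sham 2 (adjusted p = 0.0545) and with the highest row per gene. Ahsa1 missed it without Sham 2, Sham 3, IR 2 or IR 3 (adjusted p up to 0.115), and Hspb8 without Sham 1, Sham 2, IR 2 or IR 3 (adjusted p up to 0.0938). The inducible chaperone Hspa1b did not pass (0.83, SE 0.30, adjusted p = 0.118), but passed with quantile and median-of-ratios scaling and with the ribosomal protein share as a covariate. Of 23 NRF2 and antioxidant genes 2 rose and 1 fell, and 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.00190, and adjusted p = 0.520 with an estimated correlation). The members that passed were Mt2A, the quinone reductase Nqo1 (0.89, SE 0.17) and, lower, the glutathione synthetase gene Gss (-0.57, SE 0.11), and the calls of Nqo1 and Gss were lost without any Sham library, IR 2 or IR 3 (adjusted p up to 0.0966 and 0.101). The call of Gss was also lost with quantile and median-of-ratios scaling.

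Of 21 interferon genes 3 rose, and 3 adjusted over the list alone. Their mean change was 0.15 while their median was -0.026, and the list was called higher (adjusted p = 0.00513, and adjusted p = 0.623 with an estimated correlation). That call was lost with median-of-ratios scaling and with the ribosomal protein share as a covariate. Of 50 oxidative phosphorylation genes 2 rose, and 1 adjusted over the list alone (adjusted p = 5.40e-09, and adjusted p = 0.623 with an estimated correlation), a call also lost with the ribosomal protein share as a covariate. The unfolded protein response was called higher with 1 of 19 members past the threshold, Sdf2l1 (0.93, SE 0.17), and 1 adjusted over the list alone (adjusted p = 0.0135, and adjusted p = 0.623 with an estimated correlation). Its call was lost without IR 1 (adjusted p = 0.0634), where its median turned to -0.052, and that of Sdf2l1 without Sham 2, Sham 3, IR 2 or IR 3 (adjusted p up to 0.0819). Macrophage and activated microglia genes were called higher with 1 of 21 members past the threshold, the fatty acid carrier Fabp4 (1.11, SE 0.17), and 1 adjusted over the list alone (adjusted p = 0.0135, and adjusted p = 0.623 with an estimated correlation). That call was lost without Sham 1 (adjusted p = 0.0539), with quantile and median-of-ratios scaling and with the ribosomal protein share as a covariate, and that of Fabp4 without Sham 2 or IR 2 (adjusted p up to 0.0682). The fry test called none of the NRF2, interferon, oxidative phosphorylation, unfolded protein response, macrophage and oligodendrocyte lists.

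Immediate early genes, many of them transcription factors, which neuronal activity can induce, were lower in IR. Of 21 genes 5 fell, and 12 adjusted over the list alone (adjusted p = 7.82e-04, and adjusted p = 0.623 with an estimated correlation). Fos fell from 8.35 ± 1.94 to 2.08 ± 0.942 TPM and Npas4 from 3.49 ± 0.556 to 0.813 ± 0.497 TPM, and both calls were lost without Sham 2, Sham 3, IR 2 or IR 3 (adjusted p up to 0.117 and 0.0695). That of Fos was also lost with quantile and median-of-ratios scaling and with the ribosomal protein share as a covariate. Endothelial markers fell in 4 of 20 genes, and in 8 adjusted over the list alone (adjusted p = 0.00510, 0.0513 without Sham 3, and adjusted p = 0.623 with an estimated correlation). The angiopoietin receptor gene Tek and the related receptor gene Tie1 changed by -1.08 (SE 0.18) and -1.11 (SE 0.16), and lost their calls without Sham 2, IR 2 or IR 3 (adjusted p up to 0.0699 and 0.0590), Tek also with quantile and median-of-ratios scaling. Of 18 oligodendrocyte markers 1 fell, Opalin (-1.72, SE 0.39), and 3 adjusted over the list alone (adjusted p = 0.0200, and adjusted p = 0.861 with an estimated correlation). The list missed the threshold without Sham 1 or IR+NMN 2 (adjusted p up to 0.113) and with the ribosomal protein share as a covariate, and Opalin without any of the 3 Sham libraries, IR 2, IR 3 or IR+NMN 3 (adjusted p up to 0.155).

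Cell cycle genes were not called between IR and Sham (adjusted p = 0.0530), with a median of -0.40, 2 of 22 lower and 6 adjusted over the list alone. Striatal medium spiny neuron markers (adjusted p = 0.208, median -0.41, 2 of 12 lower and 3 adjusted over the list alone) were not called either. Nor were markers of hippocampus, thalamus and hypothalamus (adjusted p = 0.250, median -0.48, 3 of 12 lower, also adjusted over the list alone) and choroid plexus and ependymal markers (adjusted p = 0.127, median -0.59, 3 of 8 lower and 4 adjusted over the list alone). The fry test, which does not compare with other genes, called all 4 lists lower (adjusted p = 0.0115, 0.0123, 0.0115 and 0.00818). In each of them all 3 IR libraries lay below all 3 Sham libraries, while the median change of all genes was -0.21.

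Red blood cell genes fell in 6 of 9, and in 7 adjusted over the list alone (adjusted p = 2.38e-05, and adjusted p = 0.623 with an estimated correlation). Hemoglobin transcripts summed to 5878 ± 2992 TPM in Sham, 813 ± 85.2 in IR and 918 ± 92.8 in IR+NMN (SD, n = 3). By two-sided exact permutation test the p was 0.1 for Sham against either group, the smallest that 3 against 3 libraries allow, and 0.2 between IR and IR+NMN. Haptoglobin (Hp), the plasma protein that binds free hemoglobin and 1 of the 3 neutrophil markers above the filter, also fell in IR (-1.76, SE 0.19, adjusted p = 0.00280), a call lost with the highest row per gene. Of the 4 lymphocyte markers above the filter 1 fell, Cd4 (-0.90, SE 0.18), a gene that microglia also express in rats. Its call was lost without any Sham library or IR 2 (adjusted p up to 0.117) and with quantile and median-of-ratios scaling.

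Some other genes with large changes lie in families whose copies the authors' processing could split, which leaves their values uncertain. The same holds for genes with table rows near 0 in every Sham library and present in every other library, or the reverse. Such switched rows numbered 72 and touched 44 tested genes, among them Gng13, Rpl30 and Hba-a1. In Hba-a1 the switched row held only 8.17 of 2634 TPM in Sham, so its fall did not rest on that row. Gng13 was listed at 0 in all 3 Sham libraries, at 606 ± 230 TPM in IR and at 401 ± 157 in IR+NMN. Rpl30 fell from 453 ± 62.1 to 18.1 ± 0.744 TPM, while its relative Rpl30l2 rose from 284 ± 53.6 to 896 ± 252 TPM (adjusted p up to 0.0825 without Sham 1, Sham 2, IR 2 or IR 3). H3f3c rose from 0.944 ± 0.941 to 48.8 ± 8.40 TPM, and Ndufa10l1 fell from 15.0 ± 2.10 to 0.0554 ± 0.0511 TPM. Further genes with large rises, none with a switched row, were Grifin (4.26, SE 0.47), Asb15 (3.24, SE 0.25) and Tcra-v22.1 (2.53, SE 0.26). The respiratory chain subunit Cox7b (1.59, SE 0.29) also rose, a call lost without Sham 1, Sham 2, IR 2 or IR 3 (adjusted p up to 0.0966).

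The lists for the processes named in the series' title were not called between IR and Sham. Of the neutrophil extracellular trap machinery, proteins that neutrophils use to release webs of DNA, 1 of 14 tested genes fell, the chromatin protein Hmgb1 (-0.43, SE 0.10), and 1 adjusted over the list alone (adjusted p of the list = 0.768). Of 29 pro-apoptotic genes 1 fell, Dffa (-0.59, SE 0.14), and 0 adjusted over the list alone (adjusted p of the list = 0.758). Of 14 anti-apoptotic genes limma called 0 over all genes, and 5 were lower adjusted over the list alone (adjusted p of the list = 0.921). Of 24 NAD metabolism genes 1 fell, the transhydrogenase gene Nnt (-0.82, SE 0.19), and 1 adjusted over the list alone (adjusted p of the list = 0.652). The medians of these 4 lists were -0.18, -0.16, -0.070 and -0.097 and their means were also below 0, but above the median of all genes. The direction of the list test, which compares the test statistics of a list with those of other genes, was upwards. The call of Hmgb1 was lost without any Sham library, IR 2, IR 3 or IR+NMN 3 (adjusted p up to 0.177), as was that of Nnt (up to 0.162), and that of Dffa without Sham 2, Sham 3, IR 2, IR 3, IR+NMN 1 or IR+NMN 3 (up to 0.180). Hmgb1 and Dffa also lost it with quantile and median-of-ratios scaling and in the fit to the groups compared alone. Hmgb1 lost it with the highest row per gene and without the intensity trend, and all 3 with the ribosomal protein share as a covariate.

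Bax, a pore-forming death protein, was at 51.4 ± 4.30 TPM in Sham and 59.2 ± 6.49 in IR (adjusted p = 0.300). The protective genes Bcl2 (-0.67, SE 0.22, adjusted p = 0.0899) and Bcl2l1 (-0.35, SE 0.10, adjusted p = 0.0707) and the NAD-consuming enzyme Parp1 (-0.45, SE 0.13, adjusted p = 0.0734) did not pass over all genes. Bcl2 passed without IR 1 (adjusted p = 0.0497), Bcl2l1 without IR+NMN 2 (adjusted p = 0.0483) and Parp1 without IR 1 or IR+NMN 2 (adjusted p down to 0.0413). Nampt, the rate-limiting enzyme of NAD salvage and a gene with a switched row, was at 26.8 ± 3.89 and 21.8 ± 3.80 TPM (-0.29, SE 0.18, adjusted p = 0.306), and passed as lower with the highest row per gene (-1.26, adjusted p = 0.0215). Padi4, the enzyme that citrullinates histones in trap formation, stayed at or below 0.0396 TPM in all 9 libraries, and Il1b, Il6, Tnf and Cxcl1 were also under the filter. Complement genes were not called (adjusted p = 0.0548), with 3 of 18 higher and 1 lower, also adjusted over the list alone, a median of -0.12 and a mean of 0.039. Reactive astrocyte genes were not called either (adjusted p = 0.127). Of 21 members 1 fell, also adjusted over the list alone, and their median was -0.12 while their mean was 0.074. Gfap, the intermediate filament gene of astrocytes, was at 564 ± 212 TPM in Sham and 1549 ± 1007 in IR (adjusted p = 0.105). The neuronal gene Rbfox3 was at 133 ± 35.5 and 97.7 ± 25.7 TPM (adjusted p = 0.387) and the myelin gene Mbp at 5844 ± 2176 and 3064 ± 1211 TPM (adjusted p = 0.212).

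In all, 116 genes rose and 535 fell between Sham and IR, 651 of 10180, and 37 and 139 of them by at least 2-fold. At an unadjusted p under 0.05 there were 2884, and the 3 libraries of each group lay apart in 34.3% of genes, where chance gives 10%. The median log2 change of all genes was -0.21. The 116 rising genes lay above that median by construction, since the median was negative, and the 535 falling genes lay below it. This does not show whether the imbalance came from the shift of all genes. Scalings that removed the median shift gave 290 rising and 292 falling genes (quantile) or 276 and 285 (median of ratios). The count was 253 without Sham 1, 82 without Sham 2, 136 without Sham 3, 1138 without IR 1, 74 without IR 2, 82 without IR 3, 1128 without IR+NMN 2 and 287 without IR+NMN 3. With the ribosomal protein share as a covariate it was 432. Of the 44 named calls 19 stayed past the threshold in all 9 fits without a library.

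The comparison of IR+NMN with IR addressed the effect of NMN in rats with the occlusion. The secreted matrix protein Spp1 was at 1.85 ± 1.59 TPM in IR and 315 ± 294 in IR+NMN (6.03, SE 0.99, adjusted p = 0.0248), and the lectin Lgals3, a marker of activated phagocytes, at 1.93 ± 0.533 and 106 ± 77.9 TPM (4.85, SE 0.58, adjusted p = 0.0158). Lcn2, an iron-carrier protein of the acute response, was at 1.74 ± 1.10 and 80.9 ± 61.3 TPM (4.55, SE 0.69, adjusted p = 0.0214), and the small heat shock protein Hspb1 at 25.8 ± 21.8 and 551 ± 308 TPM (4.52, SE 0.67, adjusted p = 0.0214). The monocyte attractant Ccl2 (4.57, SE 0.85), the protease inhibitor Serpina3n (4.32, SE 0.51), the scavenger receptor Msr1 (3.32, SE 0.48), the imprinted RNA H19 (4.04, SE 0.78) and the tubulin genes Tubb6 (3.86, SE 0.49) and Tuba1c (3.14, SE 0.47) also rose. The naming rule required all 3 IR+NMN libraries to lie above all 3 IR libraries for each of these 10 genes. Each of these calls was lost without IR 2, IR 3, IR+NMN 1 or IR+NMN 3 (adjusted p up to 0.174), those of Ccl2 and H19 also without Sham 1 or Sham 2, and that of H19 without IR 1. Both were also lost with median-of-ratios scaling. With quantile normalization every named call of this contrast, here and in the following paragraphs, was lost except those of Gpt, Rac2 and Mcm5. In the fit to the groups compared alone only that of Gpt was kept.

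**Figure D1:**
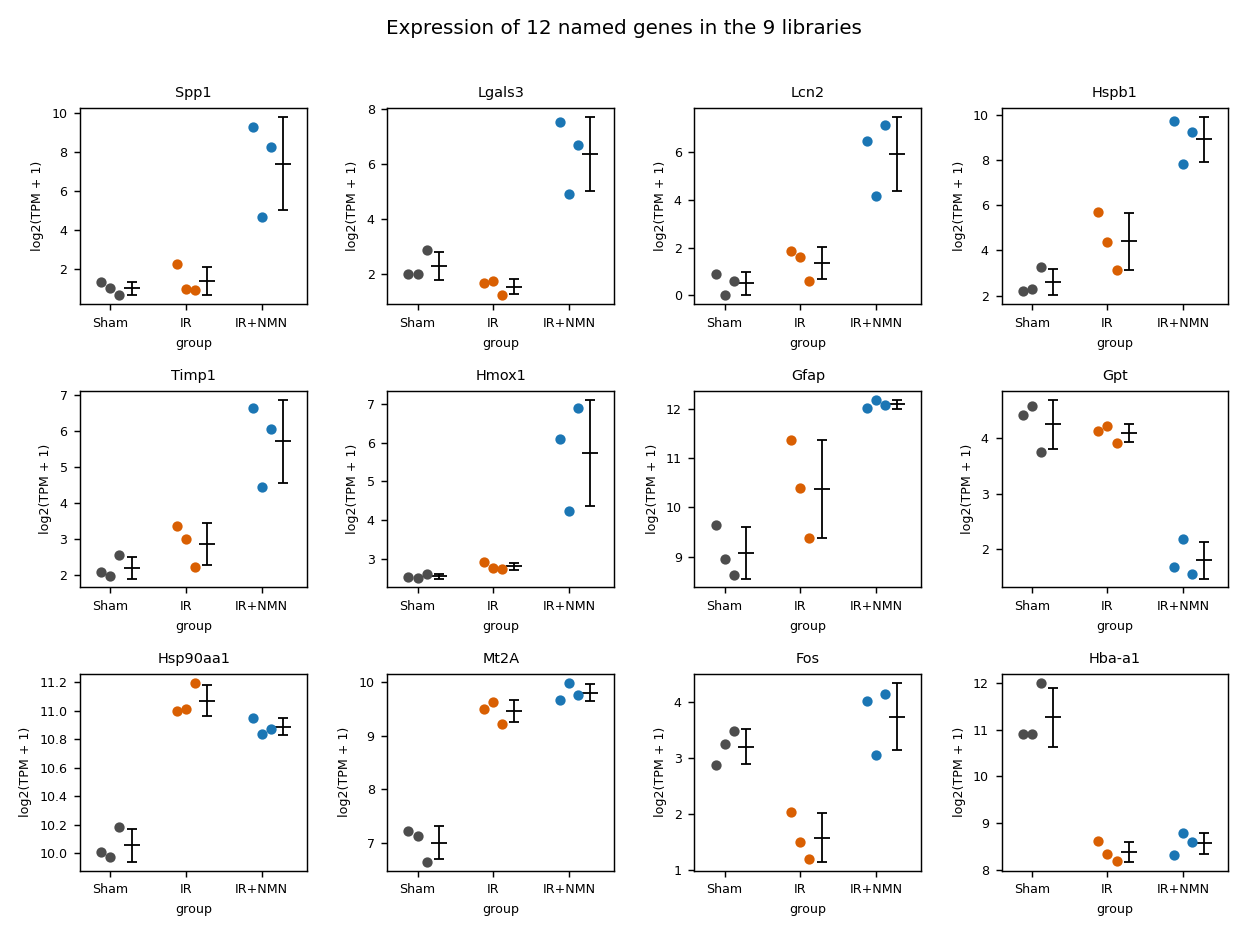
Expression of 12 named genes as log2(TPM + 1) on the vertical axes, which differ between panels and do not start at 0. Each dot is 1 of 3 libraries per group (Sham, IR, IR+NMN), and the bar with its whisker is the mean ± SD. Spp1 averaged 1.85 TPM in IR and 315 in IR+NMN, and Gpt 16.1 and 2.54 TPM.

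Reactive astrocyte genes, induced when astrocytes respond to injury, rose in 13 of 21 tested members, and in 18 adjusted over the list alone, with a median change of 1.73 (adjusted p = 4.83e-18, and adjusted p = 0.122 with an estimated correlation). Besides Serpina3n, Lcn2 and Hspb1 they included the copper carrier gene Cp (1.68, SE 0.23), Aspg (1.41, SE 0.21) and Timp1, an inhibitor of matrix proteases (2.85, SE 0.52). Gfap was at 1549 ± 1007 TPM in IR and 4357 ± 259 in IR+NMN and did not pass (1.71, SE 0.45, adjusted p = 0.0957), but passed without IR 1 (adjusted p = 0.0251) and with the ribosomal protein share as a covariate. Macrophage and activated microglia genes rose in 8 of 21, and adjusted over the list alone 14 rose and 2 fell (adjusted p = 1.43e-08, and adjusted p = 0.122 with an estimated correlation). Among them was Hmox1, the heme-degrading enzyme (2.93, SE 0.54). Cytokine and chemokine genes rose in 2 of 9, Ccl2 and Il18, and in 6 adjusted over the list alone (adjusted p = 3.95e-04, and adjusted p = 0.122 with an estimated correlation). These single-gene calls were lost without IR 2, IR 3, IR+NMN 1 or IR+NMN 3 (adjusted p up to 0.182). Timp1, Hmox1, Ccl2 and Il18 also lost theirs without Sham 1 or Sham 2 and with median-of-ratios scaling. Further losses were Hmox1 and Il18 without IR 1, Timp1 and Il18 with the highest row per gene, and Il18 with rescaling over rows with a symbol.

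Cell cycle genes rose in 8 of 22, and in 13 adjusted over the list alone (adjusted p = 4.15e-14, and adjusted p = 0.0812 with an estimated correlation). Examples were the DNA replication helicase genes Mcm5 (2.45, SE 0.22) and Mcm6 (1.52, SE 0.23), the nucleotide-producing enzyme gene Rrm2 (1.43, SE 0.20) and the proliferation marker Mki67 (1.27, SE 0.17). The mean of the list, centred on Sham, lay between -0.51 and -0.25 in IR and between 0.34 and 0.52 in IR+NMN libraries, so part of this rise started from below Sham. Interferon response genes rose in 3 of 21, and in 15 adjusted over the list alone (adjusted p = 3.10e-10, and adjusted p = 0.156 with an estimated correlation). These were the antiviral effectors Bst2 (1.49, SE 0.23), Rsad2 (1.68, SE 0.29) and Oas1a (1.41, SE 0.24). Extracellular matrix remodelling genes rose in 6 of 24, and in 11 adjusted over the list alone (adjusted p = 2.05e-08, and adjusted p = 0.129 with an estimated correlation), with the matrix glycoprotein Tnc (1.97, SE 0.35) and the crosslinking enzyme Tgm2 (1.17, SE 0.19) among them. Complement genes rose in 4 of 18, and in 6 adjusted over the list alone (adjusted p = 3.38e-04, and adjusted p = 0.245 with an estimated correlation). They were C1r, C1s and C3 of the cascade and its inhibitor Serping1 (2.26, SE 0.36). Inflammasome genes rose in 2 of 10, and in 3 adjusted over the list alone (adjusted p = 0.00426, and adjusted p = 0.122 with an estimated correlation), the adaptor Pycard (1.49, SE 0.24) and the cytokine Il18 (1.08, SE 0.21). That list call was lost with the ribosomal protein share as a covariate. Each of these genes lost its call without IR 2, IR 3, IR+NMN 1 or IR+NMN 3 (adjusted p up to 0.182), Il18 also without Sham 1, Sham 2 or IR 1, C1r without Sham 1 and Tnc without Sham 2. With median-of-ratios scaling the calls of Mcm6, Rsad2, Oas1a, Tnc, Tgm2, C1r, C3, Pycard and Il18 were lost as well. With the highest row per gene those of Oas1a, C3 and Il18 were lost.

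The trap machinery list was higher in IR+NMN than in IR. Of 14 genes 5 rose, and adjusted over the list alone 8 rose and 1 fell, with a median change of 0.45 (adjusted p = 1.28e-05, and adjusted p = 0.122 with an estimated correlation). Among the members that rose were the integrin chains Itgam (2.14, SE 0.34) and Itgb2 (1.68, SE 0.21), the GTPase Rac2 (2.11, SE 0.19) and the oxidase subunit Ncf4 (2.18, SE 0.34), all of which are expressed in phagocytes generally and not in neutrophils alone. Of the 3 neutrophil markers above the filter, Lcn2 rose, while Hp (0.72, SE 0.19, adjusted p = 0.0988) and S100a9, at 4.78 ± 1.01 and 5.47 ± 2.07 TPM (0.13, SE 0.45, adjusted p = 0.990), did not pass. The change of S100a9 turned negative with quantile normalization (-0.015). The calls of the 4 trap genes and Lcn2 were lost without IR 2, IR 3, IR+NMN 1 or IR+NMN 3 (adjusted p up to 0.119). Those of Itgam, Itgb2, Ncf4 and Lcn2 were also lost with quantile normalization. In the fit to the groups compared alone these and the call of Rac2 were lost.

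Pro-apoptotic genes rose in 2 of 29, and in 6 adjusted over the list alone, with a median change of 0.20 (adjusted p = 0.0146, and adjusted p = 0.377 with an estimated correlation). The list lost its call with a filter of 5 TPM and with the ribosomal protein share as a covariate. The members that rose were the mitochondrial pore protein Bak1, from 8.02 ± 1.35 to 16.6 ± 3.51 TPM (adjusted p = 0.0297), and the death receptor Fas, from 0.628 ± 0.168 to 2.66 ± 1.22 TPM (adjusted p = 0.0389). Bax was at 59.2 ± 6.49 and 64.9 ± 4.37 TPM (adjusted p = 0.797), Bcl2 at 1.35 ± 0.582 and 1.67 ± 0.295 TPM (adjusted p = 0.852), and Bcl2l1 at 41.3 ± 1.95 and 50.1 ± 3.85 TPM (adjusted p = 0.267). Anti-apoptotic genes were not called (adjusted p = 0.0678), with limma calling 0 of 14 over all genes and 1 higher adjusted over the list alone, and were called without IR+NMN 2 (adjusted p = 0.0495) and by the fry test (adjusted p = 0.0498). NAD metabolism genes were not called (adjusted p = 0.830). Of 24 members 1 rose, also adjusted over the list alone, the NAD-consuming enzyme Cd38, from 11.2 ± 3.61 to 27.5 ± 5.60 TPM (adjusted p = 0.0390). Nampt was at 21.8 ± 3.80 and 25.5 ± 4.38 TPM (adjusted p = 0.764), and Sirt3 and Parp1 did not pass (adjusted p = 0.755 and 0.243). The calls of Bak1, Fas and Cd38 were lost without Sham 1, Sham 2, IR 2, IR 3, IR+NMN 1 or IR+NMN 3, that of Fas also without Sham 3 or IR 1 (adjusted p up to 0.194), all 3 with median-of-ratios scaling, and that of Cd38 with the highest row per gene.

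Lower in IR+NMN than in IR as lists were homeostatic astrocyte markers (median -0.53, adjusted p = 2.20e-07, and adjusted p = 0.368 with an estimated correlation) and homeostatic microglia markers (median -0.59, adjusted p = 2.72e-05, and adjusted p = 0.305 with an estimated correlation). No member of either list passed over all genes in limma, and 3 of 16 and 6 of 13 were lower adjusted over the list alone. Neuron markers (median -0.17, adjusted p = 1.24e-04, and adjusted p = 0.421 with an estimated correlation), GABAergic interneuron markers (median -0.22, adjusted p = 8.10e-04, and adjusted p = 0.182 with an estimated correlation) and oxidative phosphorylation genes (median -0.15, adjusted p = 3.24e-08, and adjusted p = 0.463 with an estimated correlation) were also called lower. So were glutamate and GABA synapse genes (median -0.084, adjusted p = 0.0213, and adjusted p = 0.790 with an estimated correlation). In these 4 lists limma called 0 members, over all genes and adjusted over the list alone. The synapse call was lost without IR 1 or IR+NMN 1 (adjusted p up to 0.972, with a median of 0.23 without IR+NMN 1), with quantile normalization and with the ribosomal protein share as a covariate. All 6 lists were tested against all other genes, and the fry test called none of them. In none of the 6 did all IR+NMN libraries lie below all IR libraries. Homeostatic astrocyte markers averaged -0.88, 0.25 and -0.71 in IR+NMN 1 to 3, centred on Sham, and 0.31, -0.14 and 0.17 in IR 1 to 3. Their median change was -0.84 without IR+NMN 2 and -0.31 without IR+NMN 1. With a library left out the median ranged from -0.70 to -0.39 for homeostatic microglia markers, from -0.29 to -0.043 for neuron markers, from -0.30 to -0.13 for interneuron markers and from -0.27 to -0.052 for oxidative phosphorylation genes. Rbfox3 was at 97.7 ± 25.7 and 95.2 ± 40.6 TPM (adjusted p = 0.990) and Mbp at 3064 ± 1211 and 4016 ± 1779 TPM (adjusted p = 0.916), which passed as higher with the ribosomal protein share as a covariate (0.70).

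Choroid plexus and ependymal markers were called higher with 1 of 8 genes, Ttr (1.59, SE 0.22), past the threshold, also adjusted over the list alone (adjusted p = 0.0346, and adjusted p = 0.368 with an estimated correlation). That call was lost without IR 1, IR 3, IR+NMN 1 or IR+NMN 2 (adjusted p up to 0.164), with quantile normalization and with the ribosomal protein share as a covariate. Heat shock genes, called higher in IR than in Sham, were not called between IR+NMN and IR (adjusted p = 0.345), with 3 of 19 higher, also adjusted over the list alone, a median of -0.0070 and a mean of 0.40, and Hspa1b did not pass (adjusted p = 0.990). Of the 6 single genes that fell, the transaminase gene Gpt went from 16.1 ± 1.82 to 2.54 ± 0.856 TPM (-2.30, SE 0.24, adjusted p = 0.0124). The other falling genes with the smallest p were Car6 (-0.55, SE 0.098), Siglec5 (-1.27, SE 0.24), Tmem255b (-0.64, SE 0.13) and Hpd (-1.53, SE 0.31). All 5 and Ttr lost their calls without IR 2, IR 3, IR+NMN 1 or IR+NMN 3 (adjusted p up to 0.204), and Car6, Siglec5, Tmem255b and Hpd also without Sham 1 or Sham 2, the last 2 without Sham 3 and Tmem255b without IR 1. Car6, Siglec5 and Hpd also lost theirs with median-of-ratios scaling, Hpd with a pseudocount of 0.1, and Ttr with the highest row per gene (0.91, adjusted p = 0.598).

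**Figure D2:**
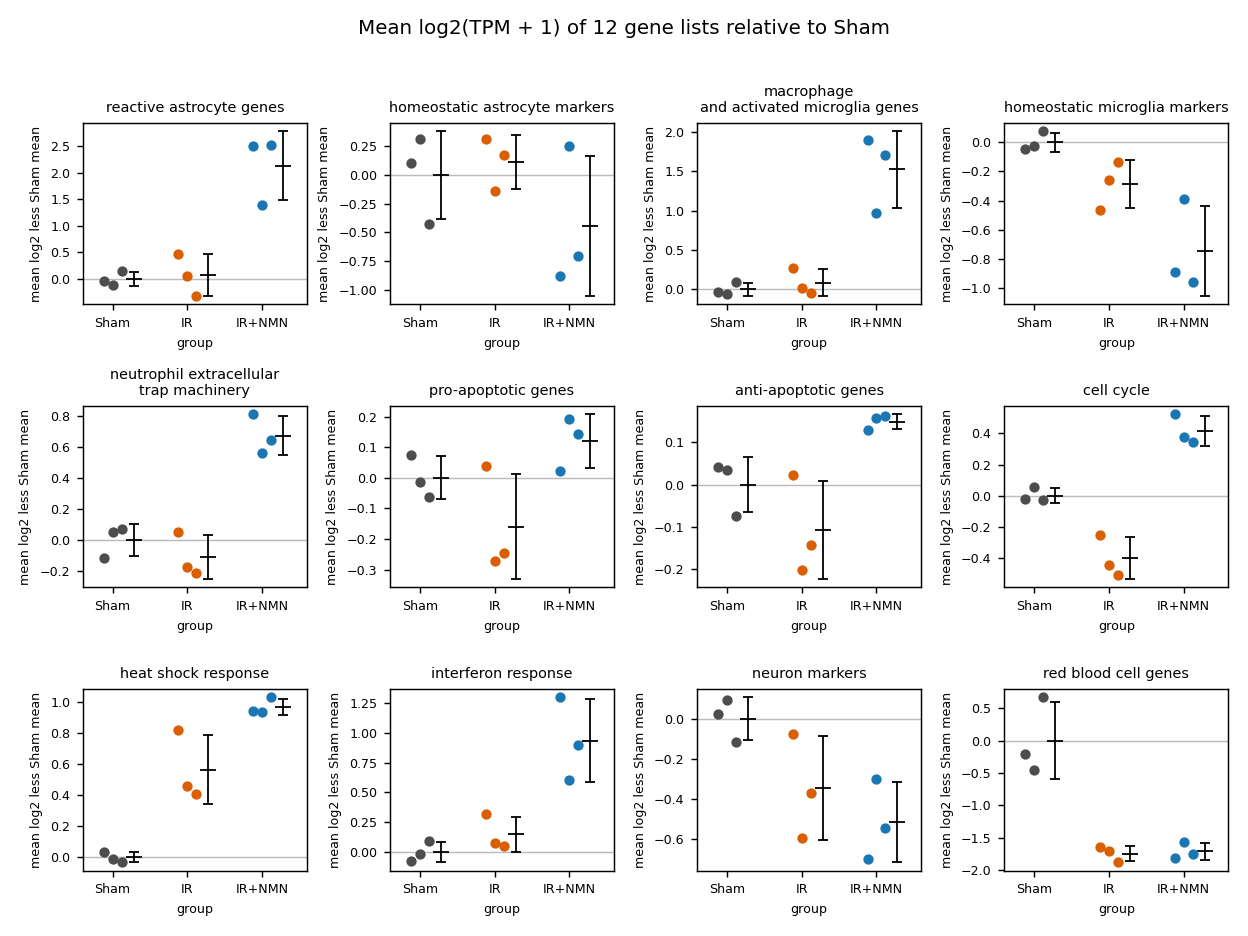
Mean log2(TPM + 1) over the tested genes of 12 gene lists, less the Sham mean, on the vertical axes, which differ between panels. Each dot is 1 of 3 libraries per group (Sham, IR, IR+NMN), and the bar with its whisker is the mean ± SD. Reactive astrocyte genes ranged from -0.31 to 0.48 in IR and from 1.39 to 2.53 in IR+NMN, and red blood cell genes averaged -1.74 in IR and -1.71 in IR+NMN.

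In all, 234 genes rose and 6 fell between IR and IR+NMN, 240 of 10180, and 146 and 3 of them by at least 2-fold. At an unadjusted p under 0.05 there were 1359, and groups lay apart in 16.9% of genes, where chance gives 10%. Another grouping of the 6 libraries, IR 1 with IR+NMN 2 and IR+NMN 3, gave 3002 genes at that unadjusted threshold. Without IR 2, IR 3, IR+NMN 1 or IR+NMN 3 limma called 0 genes, with 1015, 932, 1333 and 934 at an unadjusted p under 0.05, and without IR+NMN 2 it called 368 rising and 128 falling genes. Without Sham 1 the count was 132 and without Sham 2 it was 97. Fitted to the 6 libraries compared alone it was 2, after quantile normalization 7 (6 rising and 1 falling), after median-of-ratios scaling 73, and with the ribosomal protein share as a covariate 655. All 43 named calls of this contrast kept their direction in each of the 9 fits without a library, and 0 stayed past the threshold in all of them. The direction was largely fixed beforehand. Leaving out a Sham library cannot change this difference, and genes named for the size of their rise had to separate the groups. For Spp1 the log2 change ranged from 5.10 to 7.39 and the adjusted p reached 0.130, and for Gpt they ranged from -2.49 to -2.17 and reached 0.0994. Of the 43 calls 42 were lost in the fit to the groups compared alone, 40 with quantile normalization and 20 with median-of-ratios scaling.

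IR+NMN was also compared with Sham, to describe what differed from rats operated on without the occlusion. Spp1 rose from 1.03 ± 0.482 to 315 ± 294 TPM (adjusted p = 0.00688), Hspb1 from 5.43 ± 2.85 to 551 ± 308 TPM (adjusted p = 0.00221), Lcn2 from 0.462 ± 0.442 to 80.9 ± 61.3 TPM (adjusted p = 0.00321) and Gfap from 564 ± 212 to 4357 ± 259 TPM (adjusted p = 0.00605). Hmox1 (3.19, SE 0.54), Timp1 (3.51, SE 0.52), Lgals3 (4.09, SE 0.58), Serpina3n (4.19, SE 0.51) and Tubb6 (3.94, SE 0.49) also rose, and all 9 genes stayed past the threshold without any single library. Spp1, Hmox1 and Timp1 lost their calls with the ribosomal protein share as a covariate. Ccl2 (4.87, SE 0.85) and H19 (4.25, SE 0.78) did so too, and also without Sham 2 or IR+NMN 3 (adjusted p up to 0.0593 and 0.0640). Gng13, H3f3c, Rpl30 and Ndufa10l1, the uncertain genes above, differed from Sham in IR+NMN as well. Ttr (-2.62, SE 0.22) and Gpt (-2.45, SE 0.24) fell. The prostaglandin synthase gene Ptgds (-2.51, SE 0.65, adjusted p = 0.0441) and the growth factor gene Igf2 (-2.45, SE 0.62, adjusted p = 0.0409) fell from Sham values with a wide spread, 1078 ± 1143 and 38.9 ± 42.8 TPM. Both calls were lost without Sham 2, IR 2, IR 3, IR+NMN 1 or IR+NMN 3, and that of Ptgds also without Sham 3 or IR 1 (adjusted p up to 0.139). Both were also lost in the fit to the groups compared alone, without a filter and with the ribosomal protein share as a covariate, and that of Ptgds with median-of-ratios scaling.

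Reactive astrocyte genes rose in 17 of 21 members, and adjusted over the list alone 17 rose and 1 fell (adjusted p = 5.76e-14, and adjusted p = 0.135 with an estimated correlation). Macrophage and activated microglia genes rose in 13 and fell in 1 of 21, also adjusted over the list alone (adjusted p = 2.45e-10, and adjusted p = 0.128 with an estimated correlation), with the glycoprotein Gpnmb (3.03, SE 0.40) and the scavenger receptor Msr1 (3.33, SE 0.48) among them. Heat shock genes rose in 11 of 19, also adjusted over the list alone (adjusted p = 8.20e-11, and adjusted p = 0.128 with an estimated correlation), such as Hspb8 (1.97, SE 0.17) and the collagen chaperone Serpinh1 (1.61, SE 0.20). Hspa1b (0.75, SE 0.30, adjusted p = 0.136) passed only with quantile and median-of-ratios scaling, with library weights and with the ribosomal protein share as a covariate. Interferon genes rose in 8 of 21, and in 15 adjusted over the list alone (adjusted p = 3.62e-12, and adjusted p = 0.135 with an estimated correlation), such as Bst2 (2.58, SE 0.23) and the transcription factor Irf7 (1.38, SE 0.19). Complement genes rose in 7 and fell in 1 of 18, also adjusted over the list alone (adjusted p = 9.74e-06, and adjusted p = 0.135 with an estimated correlation), among them C1qb (1.53, SE 0.14) and C1qc (1.56, SE 0.16), chains of its first component. NRF2 and antioxidant genes rose in 5 of 23, and in 7 adjusted over the list alone (adjusted p = 5.72e-05, and adjusted p = 0.128 with an estimated correlation), with the metallothioneins Mt2A (2.81, SE 0.18) and Mt1 (2.11, SE 0.29) among them. Cell cycle genes rose in 7 and fell in 1 of 22, and 8 rose and 2 fell adjusted over the list alone (adjusted p = 4.15e-05, and adjusted p = 0.135 with an estimated correlation), with Mcm5 (1.92, SE 0.22) and the replication clamp Pcna (0.76, SE 0.11) higher. Each other gene named for these lists stayed past the threshold without any single library.

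Cytokine and chemokine genes rose in 3 of 9, and in 4 adjusted over the list alone (adjusted p = 0.00252, and adjusted p = 0.128 with an estimated correlation), Ccl2, Il18 (1.30, SE 0.21) and Cxcl16 (2.18, SE 0.51). Inflammasome genes rose in 3 and fell in 1 of 10, and 4 rose and 2 fell adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.135 with an estimated correlation), with Pycard (1.86, SE 0.24) higher and the pore protein gene Gsdme (-0.62, SE 0.14) lower. That list call was lost with quantile and median-of-ratios scaling and with the ribosomal protein share as a covariate. Unfolded protein response genes rose in 3 of 19, also adjusted over the list alone (adjusted p = 0.00252, and adjusted p = 0.397 with an estimated correlation), Sdf2l1 (1.17, SE 0.17), Creld2 (0.75, SE 0.13) and Manf (0.59, SE 0.11). Extracellular matrix genes rose in 4 and fell in 1 of 24, and 8 rose and 1 fell adjusted over the list alone (adjusted p = 5.24e-04, and adjusted p = 0.298 with an estimated correlation), with Tgm2 (1.75, SE 0.19) higher and the protease inhibitor Timp3 (-1.14, SE 0.17) lower. The matrix call was lost with the ribosomal protein share as a covariate, and the fry test called neither the matrix nor the unfolded protein list. Ccl2 lost its call without Sham 2 or IR+NMN 3 (adjusted p up to 0.0593), Creld2 too (up to 0.0544), Cxcl16 without any Sham library, IR+NMN 1 or IR+NMN 3 (up to 0.123), and Gsdme without any Sham library, IR 3, IR+NMN 1 or IR+NMN 3 (up to 0.111). Ccl2, Cxcl16 and Gsdme also lost it with the ribosomal protein share as a covariate, and Gsdme in the fit to the groups compared alone.

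Trap machinery genes rose in 6 and fell in 1 of 14, and 6 rose and 2 fell adjusted over the list alone (adjusted p = 5.24e-04, and adjusted p = 0.156 with an estimated correlation). Itgam (2.46, SE 0.34), Ncf4 (2.82, SE 0.34) and Itgb2 (1.48, SE 0.21) were higher without any single library. Pro-apoptotic genes rose in 3 and fell in 1 of 29, and 4 rose and 2 fell adjusted over the list alone (adjusted p = 0.0168, and adjusted p = 0.397 with an estimated correlation). That call was lost with a filter of 5 TPM, by the fry test and with the ribosomal protein share as a covariate. The death receptor Tnfrsf1a (1.18, SE 0.30) rose and the membrane protein Perp (-0.80, SE 0.18) fell. Both calls were lost without any Sham library, IR+NMN 1 or IR+NMN 3, that of Tnfrsf1a also without IR 2 (adjusted p up to 0.146 and 0.0981), and that of Perp with the ribosomal protein share as a covariate and in the fit to the groups compared alone. Anti-apoptotic genes were not called (adjusted p = 0.195). Of 14 members 3 rose, Bcl2a1 (1.70, SE 0.38), Mcl1 (0.58, SE 0.15) and Bag3 (0.96, SE 0.25), and 3 rose and 3 fell adjusted over the list alone. All 3 calls were lost without any Sham library or IR+NMN 3, those of Mcl1 and Bag3 also without IR 2, IR 3 or IR+NMN 1, and that of Bag3 without IR+NMN 2 (adjusted p up to 0.146). That of Bcl2a1 was lost with the ribosomal protein share as a covariate and in the fit to the groups compared alone. NAD metabolism was not called (adjusted p = 0.403), with a median of -0.068, a mean of 0.0086 and 1 of 24 genes higher, also adjusted over the list alone. That was Cd38 (1.19, SE 0.25), whose call was lost without Sham 1, Sham 3, IR+NMN 1 or IR+NMN 3 (adjusted p up to 0.0897), with the highest row per gene and with the ribosomal protein share as a covariate. Bax (0.33, SE 0.12, adjusted p = 0.105), Bcl2 (-0.46, SE 0.22, adjusted p = 0.190) and Nampt (-0.073, SE 0.18, adjusted p = 0.801) did not pass. The change of Nampt turned positive with quantile normalization (0.077), and passed as lower with the highest row per gene (-0.92, adjusted p = 0.0447).

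Lower than in Sham were homeostatic microglia markers, in 6 of 13 genes and 7 adjusted over the list alone (adjusted p = 0.00342, and adjusted p = 0.404 with an estimated correlation). The purinergic receptor gene P2ry12, a marker of resting microglia, fell from 34.7 ± 1.59 to 8.99 ± 3.62 TPM. Neuron markers fell in 4 of 24, and in 9 adjusted over the list alone (adjusted p = 1.12e-04, and adjusted p = 0.404 with an estimated correlation), with the noncoding RNA Meg3 (-1.19, SE 0.18) among them. Endothelial markers fell in 7 of 20, and in 11 adjusted over the list alone (adjusted p = 0.00739, 0.0510 without Sham 3, and adjusted p = 0.501 with an estimated correlation), with Itm2a at 64.3 ± 16.8 and 16.6 ± 2.56 TPM. Immediate early genes fell in 7 of 21, and adjusted over the list alone 8 fell and 1 rose (adjusted p = 0.0169, and adjusted p = 0.453 with an estimated correlation), a call lost without Sham 3 or IR+NMN 2 (adjusted p up to 0.144). Npas4 (-1.82, SE 0.22) and Egr4 (-1.22, SE 0.14) were among them. Striatal medium spiny neuron markers, whose mean was also below Sham in all IR libraries, fell in 3 of 12, and in 6 adjusted over the list alone (adjusted p = 0.0246, and adjusted p = 0.218 with an estimated correlation), a call lost without Sham 3 or IR+NMN 2 (adjusted p up to 0.0575). The opioid precursor Penk (-0.95, SE 0.15) was among them. P2ry12, Meg3, Itm2a, Npas4, Egr4 and Penk stayed past the threshold without any single library.

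Red blood cell genes fell in 6 of 9, and in 7 adjusted over the list alone (adjusted p = 6.49e-06, and adjusted p = 0.156 with an estimated correlation), beside the hemoglobin sums of 5878 ± 2992 TPM in Sham and 918 ± 92.8 in IR+NMN. Hp (-1.04, SE 0.19) fell as well, a call lost without Sham 2 or IR+NMN 3 (adjusted p up to 0.0626), with the highest row per gene and with the ribosomal protein share as a covariate. Glutamate and GABA synapse genes were called lower with 1 of 36 past the threshold, Cacng3 (-1.30, SE 0.30), and 0 adjusted over the list alone (adjusted p = 0.0238, and adjusted p = 0.700 with an estimated correlation). Oligodendrocyte precursor markers were called lower with 1 of 8, the growth factor receptor Pdgfra (-0.93, SE 0.23), and 3 adjusted over the list alone (adjusted p = 0.0238, and adjusted p = 0.506 with an estimated correlation). The synapse call was lost without Sham 1 or IR+NMN 1 (adjusted p up to 0.299) and the precursor call without Sham 2 or IR+NMN 1 (adjusted p up to 0.0530), and both were lost with the fry test and the ribosomal protein share as a covariate, where the synapse median was 0.33. Cacng3 and Pdgfra lost their calls with that covariate, in the fit to the groups compared alone and without Sham 2, Sham 3, IR+NMN 1 or IR+NMN 3, Cacng3 also without Sham 1 and Pdgfra without IR 3 (adjusted p up to 0.117 and 0.136).

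In all, 429 genes rose and 624 fell between Sham and IR+NMN, 1053 of 10180, and 398 of them by at least 2-fold. At an unadjusted p under 0.05 there were 3040, and groups lay apart in 33.4% of genes, where chance gives 10%. The median log2 change of all genes was -0.14. The 429 rising genes lay above that negative median by construction, and the 624 falling genes lay below it, which says nothing on the source of the imbalance. Quantile normalization gave 717 rising and 692 falling genes and median-of-ratios scaling 676 and 589. The count was 685 without Sham 1, 287 without Sham 2, 459 without Sham 3, 681 without IR 3, 374 without IR+NMN 1, 2168 without IR+NMN 2 and 276 without IR+NMN 3. It was 620 in the 6 libraries compared alone and 462 with the ribosomal protein share as a covariate. Of the 90 named calls 55 stayed past the threshold in all 9 fits without a library, and all kept their direction there. That direction was partly fixed beforehand, since genes named for the size of their change had to separate the groups.

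The response score, centred on Sham, was 2.57 ± 0.388 (SD, n = 3) in IR libraries left out of the choice of genes and 2.47 ± 0.218 (SD, n = 3) in IR+NMN libraries. The difference of -0.103 was smaller than the spread between libraries (two-sided exact permutation p = 0.8, smallest possible 0.1). It turned positive without Sham 1 (0.106) or Sham 3 (0.0444). Genes with switched rows and red blood cell genes could enter the choice, and no score without them was computed. Some of these, such as Gng13 and Rpl30, differed from Sham in both other groups. Similar scores therefore do not by themselves show a similar response to ischemia. Across genes, which are not independent replicates, the changes of IR against Sham and of IR+NMN against IR had a Pearson correlation of -0.130. Simulated draws with no group effect and the same shared IR libraries gave -0.482 (SD 0.303). The covariance was -0.0216, against -0.0330 in the simulation, a difference of 0.0114. The changes of IR and of IR+NMN against the shared Sham libraries correlated at 0.695, against 0.448 in the simulation (SD 0.335, from -0.251 to 0.969). Their covariance was 0.160 against 0.0327 (SD 0.0342, from -0.0113 to 0.181), a difference of 0.127. Both observed values lay within the simulated ranges, though the difference in covariance was larger than the simulated SD. The draws reshuffled the spread of the same 9 libraries with random signs, so a drawn group could carry a shift of its own. The extremes of 100 draws therefore cannot decide whether these values exceed those with no group effect. Of the calls against Sham, 75 genes rose in both IR and IR+NMN and 296 fell in both. The 100 simulated draws averaged 2.55 and 23.3, with ranges from 0 to 255 and from 0 to 2333. A single draw carried the whole of each average and the others gave 0, so the averages describe no typical draw. The observed counts lay within both ranges, and independent lists of these sizes would share 4.89 and 32.8. The Sham libraries were too few to split, so some or all of any excess may come from the shared controls.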

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

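All tests of explanations in the following paragraphs were chosen after the result was seen, except the counts of other splits of the 6 libraries for genes and lists, which were planned before the data were examined.

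Groups of 3 libraries were too small to test a single library against the others of its group. A signal appeared in rows with a blank symbol, which no comparison used, above the level in Sham. These rows held 0.128% ± 0.111 of the TPM in Sham, 0.405% ± 0.0482 in IR and 0.596% ± 0.189 in IR+NMN (SD, n = 3). The blank row highest in IR+NMN was listed at 0 in Sham, at 266 ± 129 TPM in IR and at 1353 ± 653 in IR+NMN (SD, n = 3). What this row encodes is unknown, and no explanation was tested.

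Table rows switched between Sham and the other groups. At a lower limit of 0.01 TPM and an upper limit of 5 TPM, 30 rows, 19 of them without a symbol, were absent in Sham alone and 42 were present in Sham alone. Of the 84 splits into 3 and 6 libraries 1, the real one, gave as many as 72 rows, and the highest other gave 3. Chance as the source is thus unlikely. It is not excluded, because the rows had been noticed by this same pattern before they were counted. A change of the whole gene was argued against by a median absolute log2 change of 0.31 (quartiles 0.17 and 0.56) in the summed genes. A strain variant, or an annotation or quantification step that differed between Sham and the others, may be involved, since 37 of 44 genes stayed within 2-fold, but these and the occlusion itself cannot be told apart, because each is shared by a whole group.

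Reactive astrocyte genes were higher in IR+NMN than in IR and were not called between IR and Sham. With the ribosomal protein share as a covariate the median log2 change of the reactive astrocyte genes was 1.92, which argues against that share as the whole cause. Reactive less homeostatic astrocyte genes differed by 2.62 between IR+NMN (2.58 ± 1.25, from 1.14 to 3.38) and IR (-0.040 ± 0.39, from -0.49 to 0.20; SD, n = 3), against a lower share of neurons as the whole cause. This difference replaced a first test on homeostatic astrocyte markers alone, whose groups overlapped (IR from -0.14 to 0.31, IR+NMN from -0.88 to 0.25) and decided nothing, so it weighs little, and a change within the astrocytes stays open. Exchanged labels, another sampled region, a larger injury and an effect of NMN cannot be told apart, since the reactive astrocyte median in IR against Sham was -0.12 and the labels give neither region nor time.

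Hemoglobin transcripts were higher in Sham than in both other groups. Alas2, a red cell gene outside the globin family, changed by -2.38 on the log2 scale between Sham and IR, which is consistent with more blood in the Sham tissue. Without the switched rows the log2 ratio of summed hemoglobin, Sham to IR, was still 2.85, which argues against rows found in Sham alone as the cause. Whether blood was removed differently between the groups is not given in the labels, and no biological explanation was tested.

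The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For IR against Sham the real split gave 651 genes and the highest other 0, and 10 lists against 17, with 5 of 10 splits reaching the real count of lists. In IR+NMN against IR the real split gave 240 genes against 0 and 17 lists against 15. In IR+NMN against Sham it gave 1053 genes against 0 and 21 lists against 19. For genes past the adjusted threshold, 1 of 10 splits, the real one, reached the real count in each comparison. The same held for lists in both comparisons involving IR+NMN. At an unadjusted p under 0.05 the real split was not always the highest. In IR+NMN against IR it gave 1359 genes, while grouping IR 1 with IR+NMN 2 and IR+NMN 3 gave 3002. For IR against Sham it gave 2884 (highest other 2434), and for IR+NMN against Sham 3040 (highest other 2494).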

How the results depend on the processing

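The highest row per gene, rescaling over rows with a symbol, leaving out genes with switched rows, the ribosomal protein share as a covariate and median-of-ratios scaling of the lists were chosen after the result was seen, and the others were planned. TPM keeps no depth, so what depth limits could not be computed. Where no reason is given, the cause was not tested.

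Of the values that answer a comparison 100 stayed the same under the alternatives, 41 moved and 2 reversed. Counts were judged by their size alone, and 1458 against 1053 genes for IR+NMN against Sham still passed as the same. So did 582 against 651 for IR against Sham with quantile normalization, though 290 rose, 292 fell and 353 calls were shared. The score stayed where its sign held, and a correlation where it moved by less than the simulated SD. Single lists and genes stayed where direction and call held. Of the values of single lists 886 stayed, 105 lost and 2 gained a call and 14 reversed. Of those of single genes 4053 stayed, 740 lost and 36 gained a call and 33 reversed.

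The count of genes changed between IR and Sham was 651. It ranged from 74 to 1138 with a library left out, and was 100 with the replicate block, 5157 with library weights, 432 with the ribosomal protein share as a covariate and 176 at a change of at least 2-fold. The count for IR+NMN against IR was 240, from 0 to 496 with a library left out, 33 with the replicate block, 7 after quantile normalization, 73 after median-of-ratios scaling, 4426 with library weights, 655 with the ribosomal protein share as a covariate, 2 with only the 2 groups compared and 149 at a change of at least 2-fold. At an unadjusted p under 0.05 limma called 1015 without IR 2, 932 without IR 3, 1333 without IR+NMN 1 and 934 without IR+NMN 3, where the adjusted count was 0. The count for IR+NMN against Sham was 1053, from 276 to 2168 with a library left out, 499 with the replicate block, 5798 with library weights, 462 with the ribosomal protein share as a covariate, 620 with only the 2 groups compared and 398 at a change of at least 2-fold. The estimate of the library weights did not converge, so its counts say little. Between libraries of the same replicate number, the deviations from the group means correlated from -0.568 to 0.492. Libraries of different numbers were not compared in this way, so these values cannot settle whether the numbers pair libraries. Whether the block fits better was not tested. It ended 22 of the 44 named gene calls of IR against Sham, 28 of 43 of IR+NMN against IR, Lcn2 and Hspb1 among them, and 18 of 90 of IR+NMN against Sham. A minimum change removes genes by construction. With an estimated correlation between genes, camera called 0 lists in IR against Sham, 0 in IR+NMN against IR and 0 in IR+NMN against Sham, where the preset one gave 10, 17 and 21 and fry 8, 14 and 19.

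The response score difference of -0.103 ranged from -0.229 to 0.106 with a library left out, and turned positive without Sham 1 (0.106) or Sham 3 (0.0444).

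Directions of list tests reversed as follows, with the list's median. The fry test compares with no other genes, which is why it turned lists lying between 0 and the median of all genes. For IR against Sham this concerned the trap machinery (-0.18 by fry, -0.18 with the ribosomal protein share as a covariate, from -0.27 to -0.069 with a library left out), pro-apoptotic genes (-0.16 by fry, from -0.26 to -0.073), anti-apoptotic genes (-0.070 by fry, -0.039 with the ribosomal protein share, from -0.17 to -0.023) and NAD metabolism (-0.097 by fry, -0.20 with a filter of 5 TPM, from -0.19 to -0.017). Between IR+NMN and IR, NAD metabolism ranged from -0.035 to 0.14 and synapse genes from -0.42 to 0.23 with a library left out. Between IR+NMN and Sham, NAD metabolism was at -0.068 by fry and -0.077 with a filter of 5 TPM (from -0.17 to -0.0034 with a library left out), and synapse genes at 0.33 with the ribosomal protein share (from -0.82 to -0.13).

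Single genes that reversed had not passed the threshold in the fit described. With quantile normalization the log2 change was 0.090 for Sirt3 (IR against Sham), -0.015 for S100a9 (IR+NMN against IR), and 0.042 for Bcl2l1, 0.077 for Nampt and 0.038 for Parp1 (IR+NMN against Sham). With median-of-ratios scaling it was 0.15 for Sirt3, 0.067 for Bcl2l1, 0.069 for Nampt and 0.063 for Parp1 in the same contrasts. With the highest row per gene it was -0.59 for S100a9 (IR+NMN against IR), and -0.0073 for S100a9 and 0.058 for Parp1 (IR+NMN against Sham). With library weights Hspa1b was at 0.41 (IR+NMN against IR). With the ribosomal protein share as a covariate the change was 0.044 for Sirt3 and -0.13 for Ccl2 (IR against Sham), -0.072 for S100a9, 0.15 for Hspa1b and 0.13 for Rbfox3 (IR+NMN against IR), and 0.26 for Nampt, 0.10 for Parp1, 0.11 for Rbfox3 and 0.45 for Mbp (IR+NMN against Sham). With a library left out the ranges were -0.17 to 0.065 for Sirt3 and -0.070 to 0.51 for Ccl2 (IR against Sham), -0.10 to 0.37 for S100a9, -0.29 to 0.24 for Hspa1b and -0.41 to 0.18 for Rbfox3 (IR+NMN against IR), and -0.18 to 0.062 for Nampt (IR+NMN against Sham).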

Other observations

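The tests of lists were planned, and this list was picked for description after the result was seen. Fibroblast and meningeal markers, which a brain sample carries when its surface is included, spread widely among Sham libraries because Sham 3 stood apart. Centred on Sham, the mean log2 value of these markers was -0.57 in Sham 1, -0.65 in Sham 2 and 1.22 in Sham 3. Their mean log2 value, centred on Sham, ranged from -0.65 to 1.22 in Sham, from -1.04 to -1.01 in IR and from -1.04 to -0.52 in IR+NMN (n = 3 each), and the list was not called between IR and Sham (adjusted p = 0.0607) or between IR+NMN and Sham (adjusted p = 0.0954). Of 15 members 1 fell in IR and 2 in IR+NMN against Sham, and 5 and 3 adjusted over the list alone.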
